A study of Rattus norvegicus with 20 samples.

How the data were processed

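Gene expression was measured in subcutaneous tissue of male Zucker diabetic fatty rats on Affymetrix Rat Gene arrays. The 20 arrays fall into 4 groups of 5, which the titles label as biological replicates: lean controls fed chow, obese rats kept on a stock diet for 6 weeks, rats given rosiglitazone and rats given resveratrol. Per the labels, the tissue was frozen in liquid nitrogen, RNA was extracted with TRIzol and a column kit with a DNase step, and 100 ng of total RNA was biotin-labelled for each array. The dose, route and duration of the drugs are not given in the sources used here. Weeks on a diet are labelled for the obese group only, so the time on a diet may differ between groups.

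The deposited table holds log2 probe set values for 36685 features, made by the authors with RMA per the submitters' processing notes, with the version not given in the sources used here. Array medians differ slightly in the table, 5 values lie below 0, and each array has its own column. The arrays carry no read depth, so their number limits the precision. Features were named with the probe table of the array. It lists 15653 features, of which 14824 carry 1 gene symbol and 829 carry several, and the other 21032 features have no listed gene. By Entrez identifier 14670 of the features with 1 symbol matched the RefSeq gene table of assembly GRCr8, which was used for names only, and 0 symbols differed. Features with 1 symbol were kept, and for the 234 genes with more than 1 such feature the feature with the highest mean over the 20 arrays was used, which left 14557 genes.

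All 20 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean per group, empirical Bayes moderation and 6 contrasts of group means. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, with no limit on the size of the difference. The obese group served as the reference for both drugs, since the series describes the treatments as given to diabetic fatty rats. The replicate numbers of the titles were not used as pairs in the reported tests: across the 30 pairs of arrays with the same number, the median correlation of their deviations from the group means was 0.03.

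A set of 41 gene lists covering lipid and energy metabolism, insulin signalling, markers of immune, vascular, stromal, muscle and epithelial cells, and stress responses was written down with 1207 members, of which 875 were measured, 5 of them through an older symbol. Lists were tested with limma's camera at its preset correlation of 0.01, two-sided, with adjustment over the 41 lists of a comparison. Beside it stand camera with a correlation estimated per list, and fry, whose directional p asks whether a list's genes move, on balance, one way and whose mixed p asks whether they change in either direction. Counts by fry are those of its directional p, adjusted over the 41 lists, unless the mixed p is named. A list score is the mean of its members' log2 values after each gene was centred on its mean over the 20 arrays. The groups, contrasts, lists, tests, thresholds and the rule for named genes were fixed before the data were examined. That rule takes, in each of the 4 main comparisons, up to 10 called genes with the largest rise and 10 with the largest fall among those whose groups do not overlap, leaving out symbols of unnamed loci and of some receptor families. It adds up to 4 members of each described list with the smallest p, and the genes Pparg, Adipoq, Lep, Fabp4, Ucp1, Pck1, Cd36, Ccl2, Tnf and Sirt1. Pparg and Sirt1 have no feature with a single symbol and so no value.

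The background level of an array is the mean log2 value of 1245 olfactory and vomeronasal receptor genes, which are silent in most tissues. The 95th percentile of their gene means was 2.77, and 7998 genes had a mean above it. Where a named gene's mean in 1 group lay below this limit, the difference is given as at least the value found with that group's arrays set to no less than the limit, beside the measured one. Single values per array, such as this level and 2 list scores, were compared between groups with exact two-sided permutation tests over all 252 assignments. The similarity of the 2 drug effects was measured across genes, beside 200 simulations of unchanged groups that share a control and beside splits of the obese arrays into disjoint sets of 2 and 3.

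Alternatives planned before the data were examined were a fit of only the 10 arrays compared, a block for the replicate number, quantile normalization, median centring, filters on dim genes, the mean of a gene's features, a test of every feature, trend and robust moderation, array weights, a limit of 1.5-fold, the skeletal muscle and B cell list scores as covariates, and leaving out each array in turn. Covariates for the background level and for the skin and glandular epithelium score, and 5 sets of left-out arrays, were chosen after seeing the data. So were the counts of shared calls in 100 simulations of unchanged drug groups, made by permuting the residual arrays, and with the disjoint sets of obese arrays.

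The procedure was tested on simulated data for rosiglitazone versus obese, with 200 changed genes among 14557. It recovered 19.4% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 100% of those changed by 2, with 4 unchanged genes called. With no gene changed, limma called 0 genes in simulated obese versus lean and resveratrol versus obese data. Each simulated value was drawn independently from a normal distribution, with the same spread of a gene in all groups. The simulation thus holds no correlation between genes and no shift of the background of an array. It cannot show how many genes would be called by chance in the measured arrays, which hold both. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.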

Results

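The series addresses how rosiglitazone, a thiazolidinedione that activates the nuclear receptor PPARG, and resveratrol, a plant polyphenol, regulate gene expression in the subcutaneous tissue of diabetic fatty rats. The data are 20 arrays, 5 each from lean, obese, rosiglitazone-treated and resveratrol-treated rats, with log2 values for 14557 named genes. Differences are given on the log2 scale with the standard error of the limma fit, and n is 5 in each group throughout.

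Obese arrays had a higher background than the arrays of either drug, and single arrays differed widely in the level of a milk protein gene. The background level was 1.72 ± 0.28 (SD) in obese, 1.49 ± 0.17 in lean, 1.36 ± 0.05 in rosiglitazone and 1.39 ± 0.03 in resveratrol arrays. It was higher in obese than in rosiglitazone arrays by 0.36 (exact two-sided permutation p = 0.00794, adjusted p = 0.0318 over 4 comparisons). It was higher than in resveratrol arrays by 0.33 (exact p = 0.0159, adjusted p = 0.0318). The excess of 0.23 over lean arrays did not pass (exact p = 0.127, adjusted p = 0.169). The interquartile range of the values was narrower in obese arrays (2.45) than in lean (2.65), resveratrol (2.72) and rosiglitazone arrays (2.76). Lalba, which encodes the milk protein alpha-lactalbumin and was chosen after its values were seen, lay between 8.35 and 10.4 in lean 3, lean 4, lean 5, obese 3 and obese 4. It lay between 4.66 and 6.04 in rosiglitazone 1, 3 and 5. In resveratrol arrays Lalba averaged 1.06 ± 0.23 (SD), with none above 1.44. By correlation with the group means, 4 arrays lay closest to another group: lean 2 to resveratrol (r = 0.989 across genes, against 0.940 with lean), obese 1 to resveratrol (0.981 against 0.961), obese 4 to lean (0.966 against 0.944) and lean 1 to obese (0.947 against 0.934). Genes are not independent replicates in these correlations. Lean 2 also lay away from the other lean arrays in Alb (5.05, the others at 7.17 or above), Ccl9 (3.76, the others at 1.92 or below) and Gpnmb (7.15, the others at 5.98 or below). Obese 4 stayed within the range of the other obese arrays in these genes, with Alb at 4.49, Ccl9 at 5.17 and Gpnmb at 8.04. Lean 1 had Alb at 7.84, Ccl9 at 1.59 and Gpnmb at 4.25. It lay on the lean side of all obese arrays, as every lean array does in genes picked for groups that do not overlap. Obese 1 had Alb at 5.04, Ccl9 at 4.39 and Gpnmb at 7.77, genes in which obese and resveratrol arrays overlap. Since Alb, Ccl9 and Gpnmb were picked under the given labels, they cannot clear lean 1 or obese 4. A mislabelled sample is not excluded for any of these 4 arrays, and every comparison keeps the labels as given.

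**Figure D1:**
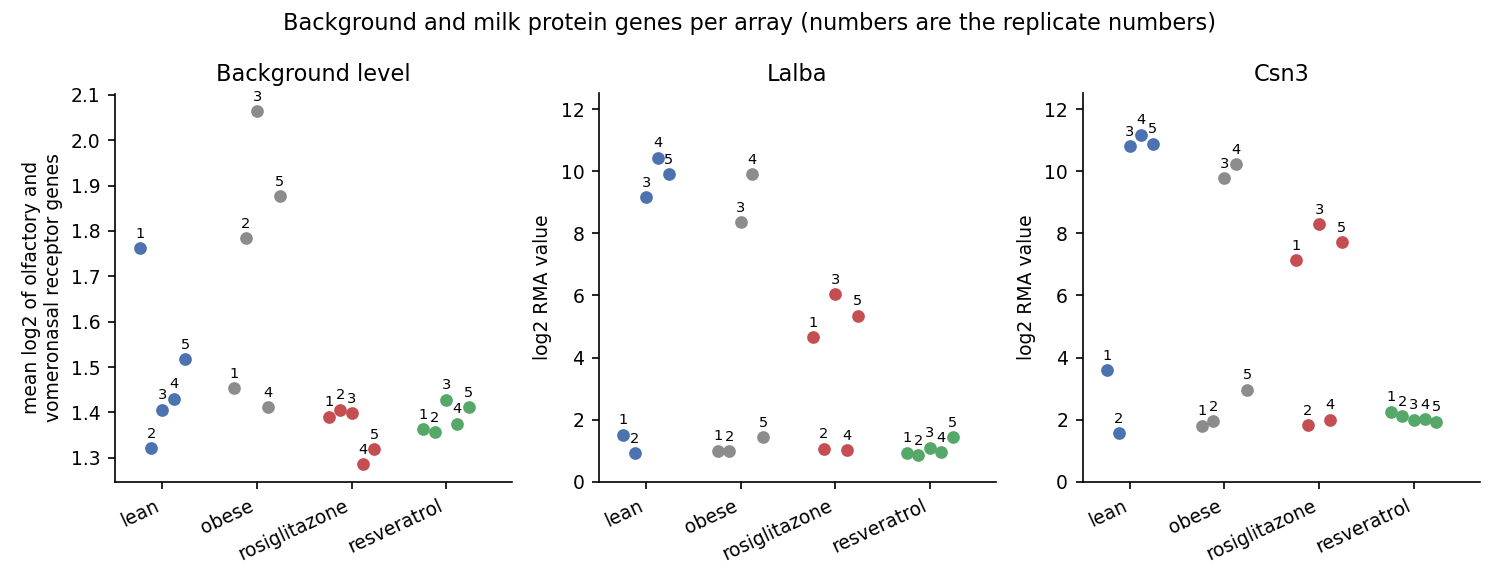
Each point is 1 array, numbered by replicate, in the lean, obese, rosiglitazone and resveratrol groups; the first panel gives the background level (mean log2 value of 1245 olfactory and vomeronasal receptor genes) and the others the log2 values of milk protein genes. Obese arrays had the highest mean background (1.72), and the 5 resveratrol arrays stayed at or below 1.44 for Lalba.

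**Figure D2:**
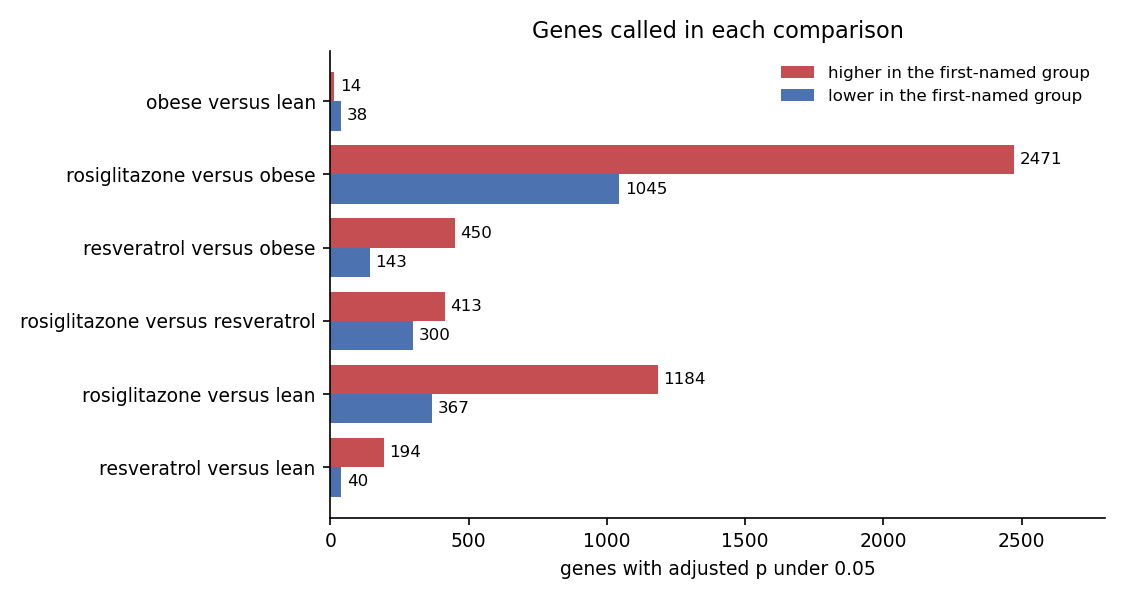
Bars give the number of genes called by limma (adjusted p under 0.05, of 14557 tested) as higher or lower in the first-named group of each of the 6 comparisons, on an axis that starts at 0. Rosiglitazone versus obese had 2471 genes higher and 1045 lower.

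The comparison of obese with lean rats describes the diabetic fatty state without a drug, in groups whose labels also name the diet differently. Gpnmb, a glycoprotein of lipid-laden macrophages, was higher in obese tissue by 2.33 ± 0.38 (adjusted p = 0.00528). The chemokine gene Ccl9 was higher by at least 1.80 (measured 2.71 ± 0.48, adjusted p = 0.00914), with a lean mean below the background limit. Lyz2, which encodes lysozyme, was higher by 1.60 ± 0.33 (adjusted p = 0.0253) and Cd68, a macrophage marker, by 1.47 ± 0.30 (adjusted p = 0.0254). Among single genes that were lower in obese tissue, Gprin3 fell by 3.08 ± 0.45, Alb, which encodes serum albumin, fell by 2.73 ± 0.38, and Acvr1c, an activin receptor of adipocytes, fell by 1.75 ± 0.26, each at an adjusted p of 0.00205. Insr, the insulin receptor, fell by 0.95 ± 0.20 (adjusted p = 0.0273). Pde3b, the phosphodiesterase through which insulin restrains lipolysis, fell by 0.94 ± 0.19 (adjusted p = 0.0254). Xbp1, a transcription factor of the unfolded protein response, fell by 1.17 ± 0.19 (adjusted p = 0.00528).

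In the same comparison the list of lipid-associated macrophage genes passed as higher (camera adjusted p = 0.000517, adjusted p = 0.525 with an estimated correlation), with 1 of 15 measured members called, 0 lower and 14 not called, and 5 higher when adjusted over the list alone. The general macrophage list also passed (camera adjusted p = 0.00296, adjusted p = 0.534 with an estimated correlation), with 2 of 24 members called higher and 22 not called, and 7 higher and 1 lower when adjusted over the list alone. Its call ended without lean 1 (adjusted p = 0.0817) and without the 4 arrays of highest background, lean 1, obese 2, obese 3 and obese 5 (adjusted p = 0.281). The list of branched-chain amino acid catabolism was lower (camera adjusted p = 1.08e-08, adjusted p = 0.525 with an estimated correlation), with 1 of 21 members called, Bcat2, which catalyses its first step and fell by 0.90 ± 0.18 (adjusted p = 0.0253), and 8 lower when adjusted over the list alone. The list of the TCA cycle and pyruvate metabolism was lower (camera adjusted p = 7.45e-06, adjusted p = 0.525 with an estimated correlation) with 1 of 22 members called, the mitochondrial isocitrate dehydrogenase Idh2, which fell by 0.86 ± 0.17 (adjusted p = 0.0206), and 5 lower when adjusted over the list alone. Insulin signalling was lower as a list (camera adjusted p = 4.58e-05, adjusted p = 0.525 with an estimated correlation) with 2 of 21 members called, and 1 higher and 6 lower when adjusted over the list alone. The oxidative phosphorylation list was lower (camera adjusted p = 7.84e-07, adjusted p = 0.534 with an estimated correlation) with 0 of 45 members called by limma in either direction, over all genes or when adjusted over the list alone. Some of these falls depended on array background in fits chosen after the results were seen. With the background level as a covariate the oxidative phosphorylation call ended (adjusted p = 0.0975), as did those of insulin signalling (adjusted p = 0.0621) and mitochondrial fatty acid oxidation (adjusted p = 0.898). Without the 4 arrays of highest background the oxidative phosphorylation call ended (adjusted p = 0.999), as did those of insulin signalling (adjusted p = 0.211) and the TCA cycle (adjusted p = 0.104). In all, 14 of 41 lists passed, 3 higher and 11 lower. With a correlation estimated per list 0 passed, with 0 at an unadjusted p under 0.05, and the lowest value was an adjusted p = 0.525 with an estimated correlation. By the directional p of fry 0 passed, with 10 at an unadjusted p under 0.05, whereas 11 passed by its mixed p.

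Obese and lean tissue differed in 52 genes (14 higher, 38 lower, 2176 at an unadjusted p under 0.05), in 39 of which the groups did not overlap. Over all genes the groups did not overlap in 1.70%, where chance gives 0.794%. Median centring of the arrays gave 5 higher and 37 lower. The balance turned with the background level as a covariate, which gave 21 higher and 15 lower with 23 of the 52 genes kept, and without lean 2, which gave 67 higher and 53 lower. With the covariate the median effect of the 52 genes, signed by the call, went from 1.19 ± 0.22 (jackknife SE) to 1.03 ± 0.19, and their median standard error from 0.211 to 0.225. Among genes fixed for reporting, Lep, which encodes leptin, differed by 1.43 ± 0.46 (adjusted p = 0.179), Pck1 by -0.46 ± 0.21 (adjusted p = 0.324) and Ccl2 by -0.49 ± 0.38 (adjusted p = 0.545). Adipoq, Fabp4, Cd36, Tnf and Ucp1 were not called. The count was 22 without lean 3, 28 without obese 5, 29 without lean 5 and 34 without lean 4. It was 87 without lean 1, 120 without lean 2, 122 without obese 1 and 146 without obese 4. It was 0 in a limma fit of only these 10 arrays (1211 at an unadjusted p under 0.05). Of the 26 called genes fixed for reporting 15, Bcat2, Cd68, Idh2, Insr, Lyz2 and Pde3b among them, lost their call without lean 3.

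The comparison of rosiglitazone with obese rats asks what a PPARG agonist changes in this tissue. Of 45 oxidative phosphorylation genes 43 rose (adjusted p = 0.0774 with an estimated correlation), and of 22 genes of the TCA cycle and pyruvate metabolism 21 rose (adjusted p = 0.0444 with an estimated correlation). Cpt1b, a carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by 3.42 ± 0.25 (10.7-fold, adjusted p = 4.08e-09). Fabp3, a fatty acid-binding protein typical of heart and muscle, rose by 4.21 ± 0.29 (18.6-fold, adjusted p = 1.48e-09). Pdhb of the pyruvate dehydrogenase complex rose by 2.19 ± 0.15 (adjusted p = 1.39e-09), and Cs, citrate synthase, by 1.89 ± 0.15 (adjusted p = 1.9e-08). Alb, the named gene with the largest rise, rose by 5.33 ± 0.38 (40.4-fold, adjusted p = 2.3e-09), to a level of 9.60 ± 0.36 (SD) from 4.26 ± 0.70. In each of these genes all 5 rosiglitazone arrays lay above all 5 obese arrays.

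Of the 45 measured genes of oxidative phosphorylation 43 rose, 1 fell and 1 was not called, with the same numbers up and down when adjusted over the list alone (camera adjusted p = 2.46e-31, adjusted p = 0.0774 with an estimated correlation). Ndufv1 of complex I rose by 2.03 ± 0.18 and Sdhb of complex II by 1.66 ± 0.14. In the list of the TCA cycle and pyruvate metabolism 21 of 22 genes rose and 0 fell, with 22 up when adjusted over the list alone (camera adjusted p = 3.33e-26). Mitochondrial fatty acid oxidation had 20 of 24 genes up and 0 down, and 20 up when adjusted over the list alone (camera adjusted p = 2.18e-22). Hadhb rose by 2.24 ± 0.20 and Acads by 1.81 ± 0.15. Both of these lists and the thermogenic list held with an estimated correlation, each at an adjusted p = 0.0444 with an estimated correlation. In the thermogenic list 9 of 19 genes rose and 1 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.00063). Its members that rose include Cidea, a lipid droplet protein (1.91 ± 0.32), Cpt1b, Fabp3 and the acyl-CoA thioesterase Acot2 (3.99-fold, adjusted p = 3.92e-08). Ucp1, the uncoupling protein of brown fat, was not called and averaged 1.57 ± 0.17 (SD) against 1.77 ± 0.33, below the 95th percentile of the background genes. Branched-chain amino acid catabolism had 20 of 21 genes up and 0 down, with 20 up when adjusted over the list alone (camera adjusted p = 6.58e-16, adjusted p = 0.0994 with an estimated correlation), among them Acat1 by 2.43 ± 0.22.

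**Figure D3:**
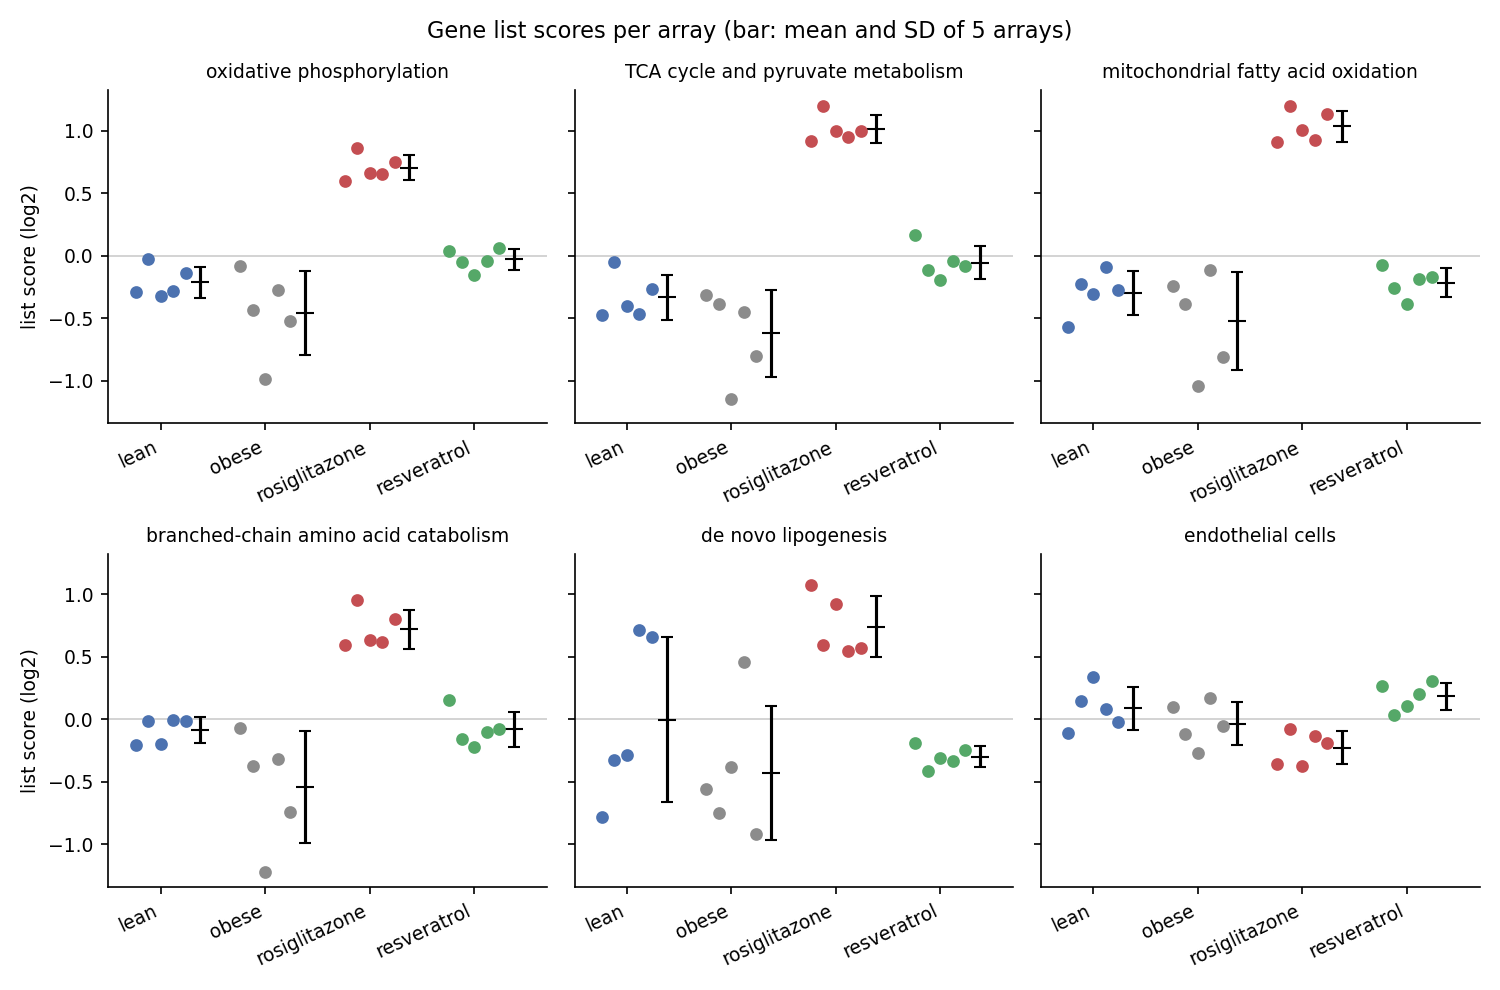
Each point is 1 array and each bar the mean and SD of 5 arrays for the scores of gene lists (mean log2 value of the members after centring each gene over the 20 arrays) in the lean, obese, rosiglitazone and resveratrol groups. The oxidative phosphorylation score averaged 0.70 in rosiglitazone, -0.03 in resveratrol, -0.21 in lean and -0.46 in obese arrays.

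The lists of lipogenesis, peroxisomal lipid metabolism and antioxidant defence also passed as higher with rosiglitazone. In de novo lipogenesis 9 of 16 genes rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 2.12e-05, adjusted p = 0.153 with an estimated correlation). Elovl6, a fatty acid elongase, rose by 3.65 ± 0.37, the malic enzyme Me1 by 3.38 ± 0.29, Pnpla3 by 2.98 ± 0.35 and the citrate carrier Slc25a1 by 1.60 ± 0.19. Peroxisomal lipid metabolism had 13 of 20 genes up and 1 down, and 15 up and 1 down when adjusted over the list alone (camera adjusted p = 4.17e-07, adjusted p = 0.0859 with an estimated correlation). Decr2 rose by 1.93 ± 0.18. Antioxidant genes rose in 16 of 28 cases and 0 fell, with 18 up when adjusted over the list alone (camera adjusted p = 2.08e-06, adjusted p = 0.257 with an estimated correlation). The mitochondrial Prdx3 rose by 2.12 ± 0.20 and Sod2 by 1.72 ± 0.20. In the list of adipocyte identity and PPARG targets 10 of 30 genes rose and 1 fell. The numbers were the same when adjusted over the list alone (camera adjusted p = 0.00567, adjusted p = 0.336 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, rose by 1.85 ± 0.21. Adipoq differed by 0.16 ± 0.11 (adjusted p = 0.270), Fabp4 by -0.04 ± 0.11 (adjusted p = 0.786), Cd36 by 0.05 ± 0.12 (adjusted p = 0.788) and Lep by -0.36 ± 0.46 (adjusted p = 0.565). Tnf was not called. Pck1, an enzyme of glyceride-glycerol synthesis, fell by 0.63 ± 0.21 (adjusted p = 0.0374). This call ended without rosiglitazone 2 or 3 or without obese 1, 2, 3 or 4, each left out alone (adjusted p from 0.0527 to 0.114).

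With rosiglitazone the matrix list passed as higher and the endothelial and pericyte lists as lower (adjusted p = 0.602, 0.599 and 0.558 with an estimated correlation). In the list of collagens and extracellular matrix 20 of 45 genes rose and 2 fell, with 22 up and 4 down when adjusted over the list alone (camera adjusted p = 0.00063, adjusted p = 0.602 with an estimated correlation). The list call ended with the background level as a covariate (adjusted p = 0.180). Col8a1 rose by 3.17 ± 0.33 and Loxl1, a collagen cross-linking oxidase, rose 5.26-fold (adjusted p = 3.53e-05). Outside that list the matrix gene Cilp rose by 4.05 ± 0.34. Dsp, which encodes the junction protein desmoplakin, rose by at least 2.84 (measured 3.40 ± 0.27) from below the background limit. Of 20 endothelial genes 7 fell, 2 rose and 11 were not called, with 7 down and 3 up when adjusted over the list alone (camera adjusted p = 0.0391, adjusted p = 0.599 with an estimated correlation). Emcn fell by 1.26 ± 0.16 and Cdh5, the cadherin of endothelial junctions, fell by 0.79 ± 0.18. Flt4, a receptor of lymphatic endothelium, rose by 1.15 ± 0.18 and Vwf, von Willebrand factor, by 1.05 ± 0.20. In the list of pericytes and smooth muscle 3 of 15 genes fell and 1 rose, with 5 down and 1 up when adjusted over the list alone (camera adjusted p = 0.0402, adjusted p = 0.558 with an estimated correlation). The endothelial call ended without rosiglitazone 1, rosiglitazone 3, obese 1 or obese 4 (adjusted p from 0.0857 to 0.116). The pericyte call ended without rosiglitazone 1, rosiglitazone 2, obese 1, obese 4 or obese 5 (adjusted p from 0.0622 to 0.140). The macrophage list did not pass (camera adjusted p = 0.675, median difference 0.08, mean -0.02, tested direction lower). Neither did the lipid-associated macrophage list (camera adjusted p = 0.546), of which 4 of 15 members fell, Gpnmb by 1.32 ± 0.38 (adjusted p = 0.017). Its median difference was 0.01, its mean -0.11 and its tested direction lower. The chemokine gene Ccl2 rose by 1.95 ± 0.38 (adjusted p = 0.000928). Large falls were seen in Nnat, which encodes neuronatin (-3.09 ± 0.35), C1qtnf9, a secreted relative of adiponectin (-2.48 ± 0.23), Pla2g2a, a secreted phospholipase (-2.40 ± 0.27), and Car4, a carbonic anhydrase (-2.02 ± 0.27).

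**Figure D4:**
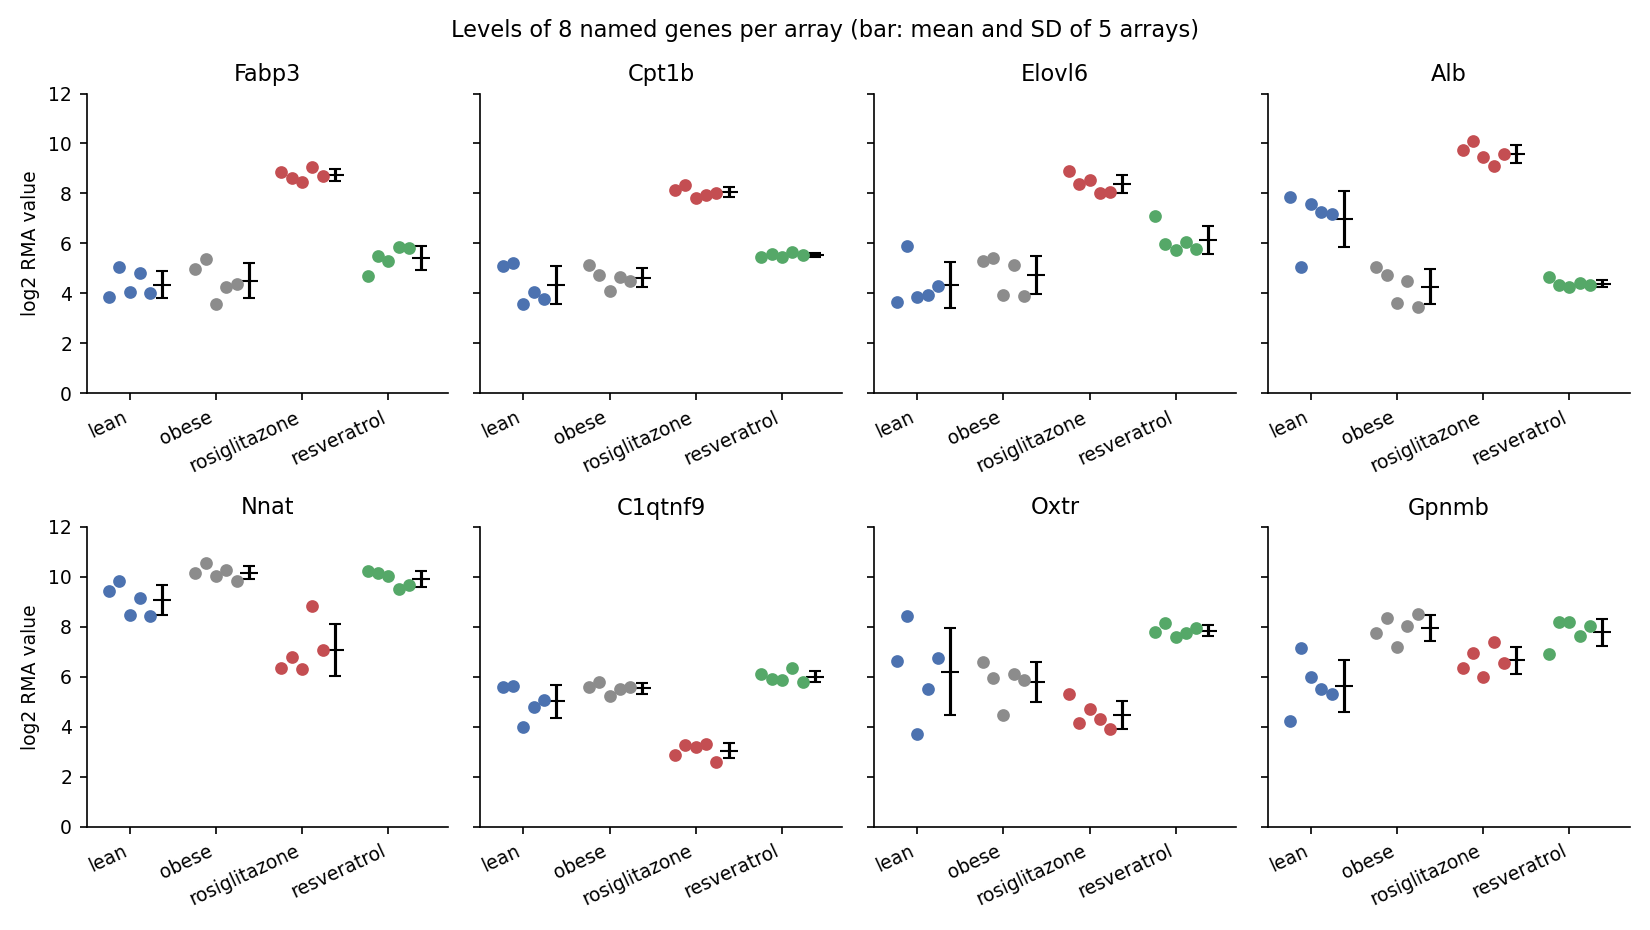
Each point is 1 array and each bar the mean and SD of 5 arrays for the log2 values of 8 named genes in the lean, obese, rosiglitazone and resveratrol groups. Alb averaged 9.60 in rosiglitazone, 6.99 in lean, 4.40 in resveratrol and 4.26 in obese arrays.

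Rosiglitazone and obese tissue differed in 3516 genes, 2471 higher and 1045 lower with rosiglitazone. Of all genes 5680 had an unadjusted p under 0.05, and 654 called genes differed at least 2-fold. In 1826 of the called genes the groups did not overlap. Over all genes this held for 13.8%, where chance gives 0.794%. In all 20 of 41 lists passed, 17 up and 3 down, 3 with an estimated correlation and 19 by fry (36 by its mixed p). The median difference was -0.32 in background genes and 0.29 in genes above background, in the same arrays whose background levels differed. In addition, 238 of the called genes that fell are background genes. Centring each array on its median moves all differences up by 0.17 and gives 3628 genes up and 344 down in place of 2471 and 1045. With the background level as a covariate 609 genes passed. The median effect of the 3516 genes, signed by the call, went in that fit from 0.68 ± 0.14 (jackknife SE) to 0.35 ± 0.05 and their median standard error from 0.181 to 0.198. Without obese 3 the count was 2307.

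The comparison of resveratrol with obese rats asks the same of the polyphenol. Of 22 genes of the TCA cycle and pyruvate metabolism 9 rose, and of 45 oxidative phosphorylation genes 7 rose and 1 fell, each list at an adjusted p = 0.645 with an estimated correlation. Idh3b, a subunit of isocitrate dehydrogenase, rose by 0.81 ± 0.17 (adjusted p = 0.0326). Dlat of the pyruvate dehydrogenase complex rose by 0.93 ± 0.21 (adjusted p = 0.0352) and Sdhb by 0.55 ± 0.14 (adjusted p = 0.0389). All 5 resveratrol arrays lay above all 5 obese arrays in each. Prkaa2, a catalytic subunit of the energy sensor AMPK, rose by 1.21 ± 0.30 (adjusted p = 0.0389) and Cpt1b by 0.91 ± 0.25 (adjusted p = 0.046). The named genes with the largest rises were Oxtr, the oxytocin receptor, by 2.06 ± 0.54 (4.17-fold, adjusted p = 0.0423) and Gatm, an enzyme of creatine synthesis, by 1.81 ± 0.45 (3.51-fold, adjusted p = 0.0389). Elovl6 rose by 1.40 ± 0.37 (adjusted p = 0.0423) and the glutathione transferase Gstk1 by 1.19 ± 0.20 (adjusted p = 0.0245).

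In the list of the TCA cycle and pyruvate metabolism 9 of 22 genes rose with resveratrol and 0 fell, and 19 rose when adjusted over the list alone (camera adjusted p = 5.51e-09, adjusted p = 0.645 with an estimated correlation). Oxidative phosphorylation had 7 of 45 genes up and 1 down, Atp5f1c, which fell by at least 1.08 (measured -1.22 ± 0.28) from a level of 3.97 ± 0.56 (SD) to below the background limit, and 34 up and 1 down when adjusted over the list alone (camera adjusted p = 1.09e-09, adjusted p = 0.645 with an estimated correlation). Mitochondrial fatty acid oxidation had 2 of 24 genes up and 0 down, and 7 up when adjusted over the list alone (camera adjusted p = 0.00599, adjusted p = 0.645 with an estimated correlation). This call ended without obese 3 (adjusted p = 0.0617). Branched-chain amino acid catabolism had 2 of 21 genes up and 0 down, and 10 up when adjusted over the list alone (camera adjusted p = 0.000149, adjusted p = 0.645 with an estimated correlation). The insulin signalling list had 1 of 21 genes up and 0 down, Pik3ca by at least 0.69 (measured 1.10 ± 0.24, from below the background limit), and 5 up when adjusted over the list alone (camera adjusted p = 0.00108, adjusted p = 0.645 with an estimated correlation). Cholesterol synthesis had 3 of 15 up and 0 down, with 8 up when adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.645 with an estimated correlation), Nsdhl by 0.83 ± 0.20 among them. Antioxidant genes were up in 2 of 28 cases and 0 fell, with 12 up when adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.645 with an estimated correlation). The cell cycle list was higher with 2 of 23 genes up and 0 down, and 7 up when adjusted over the list alone (camera adjusted p = 0.0043, adjusted p = 0.645 with an estimated correlation), and the mitotic kinase Aurkb rose at least 1.76-fold (measured 2.01-fold, adjusted p = 0.0359) from below the background limit. Fibroblast and progenitor genes were higher as a list (camera adjusted p = 0.00662, adjusted p = 0.645 with an estimated correlation) with 2 of 24 up and 0 down, Fap by 0.90 ± 0.25 and Igfbp4 by 1.12 ± 0.29, and 2 up when adjusted over the list alone. For every list of this comparison the lowest value was an adjusted p = 0.645 with an estimated correlation.

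Lists of other cell types also passed with resveratrol. The skin and glandular epithelium list was lower (camera adjusted p = 0.00219, adjusted p = 0.645 with an estimated correlation) with 0 of 23 genes called by limma, over all genes or when adjusted over the list alone. Krt19, an epithelial keratin, was lower by at least 1.21 without a limma call (measured -1.78 ± 0.69, adjusted p = 0.0973), with a resveratrol mean below the background limit. The call ended without lean 1, lean 2, obese 3 and obese 4 (adjusted p = 0.206) and without the 5 arrays highest in milk protein genes, obese 3 and obese 4 among them (adjusted p = 0.164), sets chosen after the results were seen. The score of the list averaged -0.85 ± 0.06 (SD) in resveratrol and 0.12 ± 1.17 in obese arrays (exact two-sided permutation p = 0.0873, adjusted p = 0.222 over 6 comparisons). The T and NK cell list was lower (camera adjusted p = 0.0142, adjusted p = 0.645 with an estimated correlation) with 0 of 33 genes called by limma on either count. Its call ended without obese 3 (adjusted p = 0.063). The macrophage list was higher (camera adjusted p = 0.0275, adjusted p = 0.645 with an estimated correlation) with 2 of 24 genes up and 0 down, C1qb by 1.15 ± 0.27 among them, and 3 up when adjusted over the list alone. Its call ended without resveratrol 2, resveratrol 3, obese 3 or obese 4 (adjusted p from 0.0673 to 0.111). Among the 10 named genes with the largest falls, Or4k77, Or4k49 and Or8h10c are olfactory receptor genes with mean levels at or below 2.51 in both groups. Adipoq, Fabp4, Cd36, Pck1, Tnf, Ucp1, Ccl2 (0.77 ± 0.38, adjusted p = 0.171) and Lep (0.58 ± 0.46, adjusted p = 0.386) were not called.

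Resveratrol and obese tissue differed in 593 genes, 450 higher and 143 lower with resveratrol, with 4384 at an unadjusted p under 0.05. The groups did not overlap in 378 of them, and over all genes in 6.71%, where chance gives 0.794%. In all 14 of 41 lists passed, 12 up and 2 down, 0 with an estimated correlation (0 at an unadjusted p under 0.05). By fry 4 passed (26 by its mixed p). The median difference was -0.31 in background genes and 0.28 in genes above background, and 55 of the genes that fell are background genes. Median centring, which moves all differences up by 0.13, gave 1634 up and 125 down. With the background level as a covariate limma called 0 genes (756 at an unadjusted p under 0.05), and 4 lists passed, those of oxidative phosphorylation, the TCA cycle, the cell cycle and the glandular epithelium. The count was also 0 without resveratrol 1, resveratrol 4 or obese 5 (3456, 3767 and 3931 at an unadjusted p under 0.05), so that each gene named here lost its call. It was 8 without resveratrol 2, 34 without resveratrol 3, 16 without resveratrol 5, 163 without obese 2, 15 without obese 3, 1940 without obese 4 and 2258 without obese 1.

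The direct comparison of the drugs asks where rosiglitazone and resveratrol differ, in groups whose background levels differed by -0.03 (exact two-sided permutation p = 0.373, adjusted p = 0.373 over 4 comparisons). Among list members, Cpt1b was higher with rosiglitazone by 2.52 ± 0.25 (5.72-fold, adjusted p = 9.54e-07) and Fabp3 by 3.29 ± 0.29 (9.82-fold, adjusted p = 1.26e-07). Pdhb was higher by 1.66 ± 0.15 (3.17-fold, adjusted p = 1.57e-07) and Me1 by 2.43 ± 0.29 (5.4-fold, adjusted p = 1.14e-05). Alb was higher by 5.20 ± 0.38 (36.7-fold, adjusted p = 5.13e-09). P4ha3, a collagen prolyl hydroxylase subunit, was higher by 3.19 ± 0.19. With resveratrol means below the background limit, Dsp was higher by at least 2.84 (measured 3.72 ± 0.27), Vat1l by at least 2.37 (measured 3.21 ± 0.17) and Trim63, a muscle ubiquitin ligase, by at least 2.48 (measured 3.14 ± 0.24). Lower with rosiglitazone were Oxtr (-3.37 ± 0.54, adjusted p = 0.000347), C1qtnf9 (-2.96 ± 0.23), Nnat (-2.84 ± 0.35), the proteoglycan gene Lum (-2.68 ± 0.47) and Igfbp4 (-2.27 ± 0.29). All 5 arrays of each group lay apart in each of these genes.

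Mitochondrial fatty acid oxidation had 19 of 24 genes higher with rosiglitazone than with resveratrol and 0 lower, with 21 higher when adjusted over the list alone (camera adjusted p = 1.03e-41). For oxidative phosphorylation the numbers were 31 of 45 higher and 0 lower, with 39 higher when adjusted over the list alone (camera adjusted p = 2.74e-41). For the TCA cycle and pyruvate metabolism they were 19 of 22 higher and 0 lower, with 20 higher when adjusted over the list alone (camera adjusted p = 7.69e-37). De novo lipogenesis had 7 of 16 genes higher and 0 lower, with 8 higher when adjusted over the list alone (camera adjusted p = 5.45e-10). The thermogenic list had 6 of 19 higher and 0 lower, with 8 higher when adjusted over the list alone (camera adjusted p = 6.76e-08), including Slc36a2, an amino acid transporter of brown fat, by 1.57 ± 0.35. These 5 lists and those of branched-chain amino acid catabolism, peroxisomal lipid metabolism and glycolysis also passed with an estimated correlation, with an adjusted p = 0.00245 with an estimated correlation for the thermogenic list as the lowest and 0.0367 for branched-chain amino acid catabolism as the highest. Endothelial genes were lower in 9 of 20 cases and higher in 2, with 11 lower and 2 higher when adjusted over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.0642 with an estimated correlation). Cldn5, a claudin of endothelial tight junctions, differed by -1.52 ± 0.24 and Emcn by -1.42 ± 0.16, and Flt4 was higher by 0.97 ± 0.18. Pericyte and smooth muscle genes were lower in 4 of 15 cases and 0 were higher, with 6 lower when adjusted over the list alone (camera adjusted p = 0.000277, adjusted p = 0.177 with an estimated correlation). The potassium channel gene Kcnj8 differed by -1.05 ± 0.14. The macrophage list was lower (camera adjusted p = 7.6e-05, adjusted p = 0.330 with an estimated correlation) with 2 of 24 genes lower on either count, Siglec1 by -0.90 ± 0.21 (adjusted p = 0.00855) and Cd68 by -1.03 ± 0.30 (adjusted p = 0.0484). Fibroblast and progenitor genes were lower in 6 of 24 cases and higher in 1, with 6 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.0153, adjusted p = 0.588 with an estimated correlation). Among them Sfrp2, a secreted Wnt modulator, differed by -2.00 ± 0.32 and Cd34 by -1.45 ± 0.27. This list call ended without rosiglitazone 2 (adjusted p = 0.128). Adipoq, Fabp4, Cd36, Tnf, Ucp1, Pck1, Ccl2 (1.17 ± 0.38, adjusted p = 0.0875) and Lep (-0.94 ± 0.46, adjusted p = 0.374) were not called.

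The drugs differed in 713 genes, 413 higher and 300 lower with rosiglitazone, with 1999 at an unadjusted p under 0.05 and 271 at least 2-fold. The groups did not overlap in 611 of them, and over all genes in 8.35%, where chance gives 0.794%. In all 20 of 41 lists passed, 14 higher and 6 lower, 8 with an estimated correlation and 13 by fry (25 by its mixed p). The Cd68 call ended without any 1 of the rosiglitazone arrays or of resveratrol 2, 3, 4 and 5 (adjusted p from 0.0648 to 0.144). A skeletal muscle list call (camera adjusted p = 0.00417, 1 of 21 genes higher on either count, adjusted p = 0.588 with an estimated correlation) ended without rosiglitazone 3 (adjusted p = 0.989).

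The differences of the drug groups from the obese group are both taken against the same 5 obese arrays, so they share the chance values of those arrays. Called in both comparisons with obese were 375 genes that were higher with both drugs and 119 that were lower with both, where independent sets would share 76.4 and 10.3. In addition, 2 genes were lower with rosiglitazone and higher with resveratrol, where 32.3 would be shared. In 100 simulations of unchanged drug groups limma called 0 genes in both, which leaves out the effects, whereas the independent sets leave out the shared arrays. With disjoint obese arrays for each drug the shared calls averaged 134 higher (from 0 to 570, 42.5 for independent sets) and 8.90 lower (from 0 to 42, 5.62 for independent sets). Part of the shared calls may thus come from the shared obese arrays. Obese arrays also had a higher background level than both drug groups, which the splits were not made to remove. For rosiglitazone and resveratrol the median difference was -0.32 and -0.31 in background genes and 0.29 and 0.28 in genes above background. With the background level as a covariate limma called 0 genes for resveratrol, so that no shared call remained. Across genes, which are not independent replicates, the effects of the drugs had a correlation of 0.714 and a covariance of 0.134. In simulated unchanged groups that share a control the mean covariance was 0.0234, and the correlation averaged 0.497 with a 95% range from -0.07 to 0.873 that holds the measured value. With disjoint obese arrays for each drug the correlation averaged 0.465 and ranged from 0.310 to 0.567 over 10 splits taken both ways.

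Against lean rats, rosiglitazone tissue differed in 1551 genes (1184 higher, 367 lower, 3448 at an unadjusted p under 0.05) and resveratrol tissue in 234 (194 higher, 40 lower, 2328 at an unadjusted p under 0.05). Median centring, which moves the differences of rosiglitazone from lean by 0.10, gave 1450 higher and 205 lower there. The groups did not overlap in 9.70% and 3.46% of all genes, where chance gives 0.794%. Of the 52 genes that differed between obese and lean rats, 38 were called in the opposite direction with rosiglitazone, 10 with resveratrol and 0 further in the same direction with either in the limma fit. Of the 52 genes, 11 and 26 still differed from lean in the obese direction. These genes were selected on the obese arrays that also serve as the drug reference, which pushes them towards the opposite direction. In 100 simulations that kept the lean difference and left the drug groups unchanged, at most 1 selected gene was called opposite. These could hardly give more, since limma called any gene for rosiglitazone in only 3 of them and for resveratrol in 4. They also selected 1032 genes on average (median 588.5) in place of 52. They thus cannot show how far the shared arrays raise the measured counts. With disjoint obese arrays for selection and reference 303 genes were selected on average (median 28.5, from 0 to 2344). Of these 39.9 were called in the opposite direction with rosiglitazone (median 7.5, from 0 to 340) and 1.40 further in the same direction. With resveratrol 0.450 were called in the opposite direction (median 0, from 0 to 3) and 0 further. In the same fits limma called 2584 genes with rosiglitazone on average. The count of 10 for resveratrol is thus not separated from the sharing of arrays. How much the sharing adds to the count of 38 for rosiglitazone is not settled, and the splits also have fewer arrays to call with. Alb illustrates the case of rosiglitazone: its level of 6.99 ± 1.12 (SD) in lean tissue was 4.26 ± 0.70 in obese, 9.60 ± 0.36 with rosiglitazone and 4.40 ± 0.15 with resveratrol. Because the obese arrays enter both differences, the correlations across genes of -0.488 for rosiglitazone and -0.441 for resveratrol are set beside those of simulated unchanged groups, -0.493 and -0.480. With disjoint obese arrays they averaged -0.209 (from -0.405 to 0.09) and -0.121 (from -0.446 to 0.197). The count of 234 for resveratrol against lean was 35 without lean 4, 67 without lean 3, 86 without lean 5, 89 without lean 1 and 989 without lean 2. It was 64 without resveratrol 2, 86 without resveratrol 4, 105 without resveratrol 3 and 147 without resveratrol 1. It was 0 with the glandular epithelium score as a covariate (1103 at an unadjusted p under 0.05 in limma). In that fit the median effect of the 234 genes, signed by the call, went from 1.04 ± 0.20 (jackknife SE) to 0.76 ± 0.37, and their median standard error from 0.232 to 0.248. The score was lower in resveratrol than in lean arrays by 1.62 (exact two-sided permutation p = 0.0159, adjusted p = 0.0952 over 6 comparisons).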

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

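The counts over other splits of the arrays were planned before the results were seen, whereas the tests of the 3 patterns weighed here, on milk protein genes, on resveratrol and on mitochondrial genes, were chosen after their results had been seen.

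Milk protein genes (Lalba, Csn1s1, Csn2 and Csn3, chosen after their values were seen) were high in single arrays of 3 groups of male rats and near the background in resveratrol arrays, where Csn3 averaged 2.07 ± 0.13 (SD, n = 5) and Lalba did not exceed 1.44. Krt14, a keratin of skin, did not exceed 3.10 in the 5 arrays with the most milk protein signal. It reached 6.16 in rosiglitazone 3, which ranked 6 in that signal (mean of the milk protein genes 7.12). Since that array also holds milk protein signal, Krt14 cannot decide whether some samples hold skin. Glandular tissue in some samples is a candidate source: the 5 arrays highest in these genes, lean 3, lean 4, lean 5, obese 3 and obese 4, were also the 5 highest in other epithelial genes (5 shared arrays, which chance would give with a probability of 6.45e-05). An effect of resveratrol on such tissue cannot be told apart from the sampling of the tissue. The skin and glandular epithelium score did not differ from that of obese arrays beyond the adjusted threshold (exact two-sided permutation p = 0.0873, adjusted p = 0.222 over 6 comparisons) and its level varied between arrays of the other groups.

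The 593 genes called in resveratrol versus obese had a median effect of 0.71 ± 0.15 (jackknife SE, signed by the call) in groups that also differed in background level. Glandular tissue content as the whole cause is argued against, since with the skin and glandular epithelium score as a covariate the median effect was 0.67 ± 0.14, although limma then called 1 gene. The calls ended through a slight fall of the effects and a slight rise of the median standard error, from 0.181 to 0.190, together: the new standard errors alone left 193 calls and the new effects alone 201. The background level of the obese arrays may account for a part or all of the calls. With it as a covariate the median effect was 0.353 ± 0.0879 at a median standard error of 0.188, and limma called 0 genes (756 at an unadjusted p under 0.05, lowest adjusted p = 0.822). The calls ended because the effects shrank, as the new effects alone left 0 calls in limma and the new standard errors alone 569. An effect of resveratrol cannot be told apart from the background level here, as the obese arrays hold most of the high background levels. The 86 members of the lists of oxidative phosphorylation, the TCA cycle and fatty acid oxidation went from a median of 0.49 ± 0.19 to 0.15 ± 0.11 in that fit.

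Mitochondrial and fatty acid oxidation genes rose with rosiglitazone against obese, by a median of 1.39 ± 0.21 (jackknife SE) over the same 86 genes, of which 80 were called. The background level as the whole cause is argued against by a median of 1.09 ± 0.15 with 66 genes called when it was a covariate, and skeletal muscle in some samples by a median of 1.41 ± 0.24 with 79 called when its score was a covariate. Scaling of the arrays is argued against by a median of 1.19 ± 0.14 after quantile normalization and 1.57 ± 0.26 after median centring. In the comparison of rosiglitazone with resveratrol, whose background levels differed by -0.03, the median was 0.91 ± 0.10 with 65 genes called. A higher share of adipocytes would raise the 28 genes outside the pattern from the list of adipocyte identity and PPARG targets by about as much. Their median was 0.17 ± 0.17 (jackknife SE, SD of the genes 0.96), and 4 of the 28 rose that far. These genes cannot settle the share, since rosiglitazone can change PPARG targets directly. Adipoq, Fabp4 and Cd36 already averaged 10.7 or more in obese arrays, and whether such values can rise further was not tested. The tests of the single lists were planned, whereas the pooled set of 86 genes and its tests of causes were chosen after the results were seen. A response to rosiglitazone as the cause of the rise thus remains a hypothesis, found and tested on the same data.

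Other ways to divide the 10 arrays of a comparison into groups of 5 were counted over 100 of the 126 possible splits, the labelled one included. Chance is unlikely to account alone for the genes of rosiglitazone versus obese, where only the labelled split of 100 gave as many (3516, highest other 1339). The same holds for resveratrol versus obese (593, highest other 1). So it does for rosiglitazone versus resveratrol (713, highest other 9) and rosiglitazone versus lean (1551, highest other 550). For resveratrol versus lean 2 splits gave as many, and 1 of them gave more than the labelled groups (234, highest other 247). Since 1 of 100 is the lowest share these draws can give, chance is not fully excluded for any of these counts. Chance is not excluded for the genes of obese versus lean, where 10 splits gave as many as the 52 found and the highest other gave 1672. That points to a structure of the samples: the 5 highest of the other splits, with 491 to 1672 genes, are also the 5 of 99 that keep together lean 1, obese 2, obese 3 and obese 5, the 4 arrays with the highest background levels (1.76 to 2.06). With the background level as a covariate 36 genes (21 higher, 15 lower) passed in the labelled comparison. For the gene lists of rosiglitazone versus obese no other split drawn gave as many (20 lists, highest other 19, median of the others 13). Splits that ignore the labels thus pass many lists by camera at its preset correlation, and the labelled count lies only just above the highest of them. Chance is not excluded for the lists of obese versus lean with 18 splits (14, highest other 19, median 9), of resveratrol versus obese with 12 (14, highest other 18, median 9) and of rosiglitazone versus resveratrol with 9 (20, highest other 23, median 11).

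Single arrays stood far from the other 4 of their group in 22 of 354 groups of values tested, where chance gives about 1 in 20, or 17.7. Obese 3 and rosiglitazone 3 were such arrays 4 times each and lean 2 was 3 times. In obese 3, Atp5f1c was high (4.94, nearest array 3.95), and Cdh5 (7.90, nearest 8.36), Fap (3.08, nearest 3.95) and Trem2 (3.25, nearest 4.77) were low. In rosiglitazone 3, Krt14 (6.16, nearest 3.08), Krt1 (5.31, nearest 2.10) and the skeletal muscle score (1.94, nearest -0.06) were high and Kcnj8 (3.65, nearest 4.01) was low. In lean 2, Ccl9 was high (3.76, nearest 1.92) and Alb (5.05, nearest 7.17) and Xbp1 (7.82, nearest 8.73) were low. Lean 1 was high in Lgals12 (7.52, nearest 6.81) and lean 3 in the skeletal muscle score (0.66, nearest -0.05). Rosiglitazone 4 was high in Angpt4 (3.98, nearest 3.39) and Slc36a2 (6.07, nearest 5.25), rosiglitazone 2 was high in Acadsb (8.86, nearest 8.39) and rosiglitazone 5 was low in Pdhb (7.83, nearest 8.01). Resveratrol 1 was high in Elovl6 (7.11, nearest 6.07), and resveratrol 2 was low in Cldn5 (4.57, nearest 5.09) and Pik3ca (2.43, nearest 3.60). Obese 4 was high in Ackr4 (4.46, nearest 3.53) and obese 1 was low in Or8h10c (1.45, nearest 2.11).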

How the results depend on the processing

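The covariates for the background level and the glandular epithelium score and the sets of 2, 4 or 5 left-out arrays were chosen after the results had been seen, and the other alternatives before. Of the results of genes named by rule, each 1 gene in 1 comparison, 157 were called, and 0 reversed in direction under any alternative. A call was lost under at least 1 alternative in 26 of 26 called genes for obese versus lean, 9 of 53 for rosiglitazone versus obese, 33 of 33 for resveratrol versus obese and 1 of 45 for rosiglitazone versus resveratrol. A call was gained under at least 1 alternative by 3 uncalled genes for obese versus lean (Lep, Lgals3 and Trem2), 1 for rosiglitazone versus obese (Adipoq, only with median centring, 0.33), 1 for resveratrol versus obese (Tnf) and 2 for rosiglitazone versus resveratrol (Ccl2 and Lep). Array background limits what dim genes show, since 7998 of 14557 genes lie above the 95th percentile of the background genes. The cause was not tested for the changes given here, apart from the end of the resveratrol versus obese calls with the background or glandular covariate, and a test of every feature or of bright genes adjusts over another number of tests.

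For obese versus lean (52 genes) limma called 0 genes in a fit of only the 10 arrays (1211 at an unadjusted p under 0.05), 31 features when all were tested, 259 without lean 2 and obese 4, and 772 without lean 1, lean 2, obese 3 and obese 4. It called 0 without lean 1, obese 2, obese 3 and obese 5 (1128 at an unadjusted p under 0.05) and 0 without lean 3, lean 4, lean 5, obese 3 and obese 4 (934). Leaving out 1 array gave from 22 (lean 3) to 146 (obese 4), with 28 without obese 5, 29 without lean 5, 34 without lean 4, 87 without lean 1, 120 without lean 2 and 122 without obese 1. Median centring gave 5 higher and 37 lower, and quantile normalization 24 higher and 41 lower, in place of 14 and 38. The background level as a covariate gave 21 higher and 15 lower.

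For rosiglitazone versus obese (3516 genes) the count was 2260 with only the 10 arrays, 2296 with quantile normalization, 5512 of all features and 2326 at 1.5-fold or more. It was 2163 with the B cell score as a covariate, 609 with the background level as a covariate (median effect of the called genes 0.35 in place of 0.68), 953 without lean 1, obese 2, obese 3 and obese 5, and from 2307 (without obese 3) to 4310 (without obese 4). Median centring gave 3628 higher and 344 lower in place of 2471 and 1045.

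For resveratrol versus obese (593 genes) limma called 2 genes with only the 10 arrays, 30 with quantile normalization, 1759 with median centring (1634 higher and 125 lower in place of 450 and 143), and 918 among the brighter genes. It called 0 of all features (9234 at an unadjusted p under 0.05), 41 with array weights, 179 with the skeletal muscle score, 0 with the background level (756) and 1 with the glandular score as a covariate. It called 2174 without lean 2 and obese 4, 44 without lean 1 and obese 3, 44 without the 5 arrays highest in milk protein genes, and 0 without lean 1, obese 2, obese 3 and obese 5 (1380 at an unadjusted p under 0.05). Leaving out 1 array gave from 0 (resveratrol 1, resveratrol 4 or obese 5, with 3456, 3767 and 3931 at an unadjusted p under 0.05) to 2258 (obese 1), with 8, 34 and 16 without resveratrol 2, 3 and 5, 163 without obese 2, 15 without obese 3 and 1940 without obese 4.

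For rosiglitazone versus resveratrol (713) the count was 1279 with only the 10 arrays, 1398 with array weights, 1154 without lean 1, lean 2, obese 3 and obese 4, 1113 without lean 1, obese 2, obese 3 and obese 5, and from 543 to 636 without 1 array. For rosiglitazone versus lean (1551) it was 2582 with array weights, 912 without lean 3, lean 4, lean 5, obese 3 and obese 4, and from 1108 to 1993 without 1 array, with 1450 higher and 205 lower by median centring in place of 1184 and 367. For resveratrol versus lean (234) it was 358 among the brighter genes, 106 of all features, 1294 with array weights and 360 with the B cell score. It was 0 in limma with the glandular score as a covariate (1103 at an unadjusted p under 0.05). It was 1015 without lean 2 and obese 4, 1314 without lean 1, lean 2, obese 3 and obese 4, and 0 in limma without lean 3, lean 4, lean 5, obese 3 and obese 4 (1642 at an unadjusted p under 0.05). Leaving out 1 array gave from 35 (lean 4) to 989 (lean 2), with 67, 86 and 89 without lean 3, 5 and 1 and 64, 86, 105 and 147 without resveratrol 2, 4, 3 and 1.

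For the gene lists, obese versus lean (14) gave 0 with an estimated correlation (0 at an unadjusted p under 0.05), and 0 by the directional p of fry (10). It gave 8 with the background level as a covariate, 8 without lean 1, obese 2, obese 3 and obese 5, and from 12 to 18 without 1 array. Rosiglitazone versus obese (20) gave 3 with an estimated correlation and from 17 to 20 without 1 array. Resveratrol versus obese (14) gave 0 with an estimated correlation in camera (0 at an unadjusted p under 0.05), 4 by fry and 8 with quantile normalization. It gave 4 with the background level, 9 without lean 1 and obese 3, 7 without lean 1, obese 2, obese 3 and obese 5, and from 9 (obese 3) to 16 without 1 array. Rosiglitazone versus resveratrol (20) gave 8 with an estimated correlation, 13 by fry, and from 18 to 22 without 1 array. The correlation of the drug effects (0.714) was 0.465 with disjoint obese arrays for each drug, 0.563 among the brighter genes and from 0.619 to 0.769 without 1 array. The reversal correlation of rosiglitazone (-0.488) was -0.209 with split obese arrays, -0.311 among the brighter genes and from -0.596 to -0.332 without 1 array. That of resveratrol (-0.441) was -0.121 with split obese arrays, -0.148 among the brighter genes and from -0.584 to -0.222 without 1 array. With the replicate number as a block, although the numbers do not pair the arrays, the gene counts were 45, 3362, 500, 699, 1537 and 264 and the list counts 16, 20, 14 and 22.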

Other observations

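The values in this part were read after the results had been seen, except for the list tests, which were planned. Among lists not described so far, interferon-stimulated genes were lower as a list in obese than in lean tissue (camera adjusted p = 0.00296, adjusted p = 0.534 with an estimated correlation), with 0 of 27 genes called by limma over all genes or when adjusted over the list alone. That call ended with the background level as a covariate (adjusted p = 0.0621). With rosiglitazone 9 of the 27 rose against obese and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0191, adjusted p = 0.602 with an estimated correlation). This list call ended without rosiglitazone 1 (adjusted p = 0.278) and with the background level as a covariate (adjusted p = 0.143). The sirtuin and AMPK list was higher with rosiglitazone (camera adjusted p = 0.00974, adjusted p = 0.410 with an estimated correlation), with 8 of 20 genes up and 0 down and 9 up when adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial biogenesis, rose by at least 0.25 (measured 0.75 ± 0.16, adjusted p = 0.0016) from below the background limit. Tfam, a mitochondrial transcription factor, rose by 0.94 ± 0.20 (adjusted p = 0.00241). The list call ended with the background level as a covariate (adjusted p = 0.502) and with quantile normalization (adjusted p = 0.0783), and Tfam lost its call with that covariate (0.27).

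Among lists that mark the handling of tissue or added cell types, those of handling and of lymph node did not pass. Lists of other cell types, such as macrophages, fibroblasts and endothelial cells, passed in some comparisons, as given above. The list of immediate early and heat shock genes did not pass in any of the 4 main comparisons (camera adjusted p = 0.168 for obese versus lean, 0.924 for rosiglitazone versus obese, 0.216 for resveratrol versus obese and 0.176 between the drugs). The B and plasma cell list, a marker of lymph node, did not pass either (camera adjusted p = 0.528, 0.344, 0.457 and 0.509 in the same order). The skeletal muscle list passed only between the drugs, and in the other 3 comparisons its camera adjusted p was 0.837, 0.532 and 0.155. The skin and glandular epithelium list did not pass in obese versus lean (camera adjusted p = 0.116) or rosiglitazone versus obese (0.414). Between the drugs it was higher with rosiglitazone (camera adjusted p = 0.0358, adjusted p = 0.622 with an estimated correlation, 1 of 23 genes higher on either count). This call ended without rosiglitazone 3, resveratrol 1 or resveratrol 2 (adjusted p from 0.0516 to 0.679).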
